A study of Homo sapiens with 9 samples.

How the data were processed

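Polyadenylated RNA of MCF10A cells was sequenced in 9 libraries, 3 for each of 3 groups, named by the labels as cells with an empty vector (MOCK), wild-type HER2 (WT) and HER2d16 (SP16). Per the labels, RNA was isolated with TRIzol and RNeasy columns, and libraries were made with the KAPA RNA HyperPrep kit. The labels give every library the same batch and do not say whether the replicate numbers mark days or cultures. Per the submitters' processing notes, the software named is bcl2fastq 2.20, STAR 2.7.1a and RSEM 1.3.2 with GRCh38; the role of each program and the annotation release are not given in the sources used here. As deposited, each library has a table of read counts per gene with 3 count columns, for both strands together, the strand of the gene and the opposite strand, below 4 lines of reads not assigned. A further deposited table per library, at gene level, holds RSEM's expected count, TPM and estimated length of each gene. The deposited counts on the strand of the gene were used for all tests, the deposited expected counts for an alternative, the deposited lengths for the transcript lengths reported, and the deposited TPM values were not used for any printed result.

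Reads assigned to genes on their own strand numbered 20809481, 48892784 and 30279911 in the empty-vector libraries, 36319220, 32409412 and 13407509 with HER2WT, and 22844736, 16179803 and 23404891 with HER2d16. Of all reads, 20.4 to 23.6% were left out, 10.95 to 12.1% because they mapped to several places and 2.27 to 5.17% because they did not map. Levels of genes with close paralogs or copies, such as keratins, histones, CXCL chemokines, SERPINB3, SERPINB4, ribosomal proteins and mitochondrial genes, are therefore uncertain. The own strand held 95.7 to 96.02% of the reads on either strand. The tables list 60609 genes, of which 60295 have a symbol in the name table used, 58502 are in GENCODE 29, which gave coordinates on GRCh38, and 30701 have reads. After edgeR's filterByExpr, 14296 genes were tested.

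Genes were tested in edgeR 4.0.16 (R 4.3.3) with TMM scaling, a quasi-likelihood fit (glmQLFit, robust) of all 9 libraries with a mean per group, and two-sided F tests of HER2d16 against empty vector, HER2WT against empty vector, and HER2d16 against HER2WT. The common dispersion was 0.0029. P-values were adjusted by Benjamini-Hochberg over all genes tested and called below 0.05; every adjusted p of a gene is from edgeR and every adjusted p of a list from limma 3.58.1. Levels are CPM with TMM-scaled library sizes. Where a group had 0 reads of a gene, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 reads the ratio is given with its 95% counting interval. Principal components were taken from log2 CPM of the tested genes.

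The 29 gene lists, with 1033 entries of which 1032 matched a gene, were integrin subunits, focal adhesion and integrin signalling, hemidesmosome and epidermal adhesion, basement membrane matrix, interstitial matrix, matrix proteases and inhibitors, mesenchymal and EMT regulators, epithelial junctions, luminal mammary markers, basal mammary markers, keratinocyte differentiation, ERBB receptors and ligands, MAPK pathway output, FOXO targets repressed by PI3K and AKT, proliferation, interferon response, NF-kB and inflammatory cytokines, TGF-beta targets, YAP and TAZ targets, cholesterol and lipid synthesis, glycolysis and hypoxia, unfolded protein and integrated stress response, p53 targets, fibroblast markers, endothelial markers, immune markers, mitochondrially encoded genes, ribosomal proteins and replication-dependent histones. The lists, the tests, the naming rule and most alternative settings were fixed before the data were examined. Lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the 29 lists of a comparison, and again with the correlation estimated per list. The p of the second form could rise even where the estimate lay below 0.01. A call lost there need not reflect correlation between genes. Camera compares a list with all other genes, while fry, run beside it, tests whether the genes of a list move 1 way on balance and does not compare them with other genes. Fibroblast, endothelial and immune markers were included as signs of other cells, mitochondrial and ribosomal genes as signs of RNA quality, and histones as a sign of polyA selection.

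Named genes follow a rule: ERBB2; per comparison the 10 largest rises and falls among called protein-coding genes with a mean log2 CPM of at least 2 and no overlap between groups; per list and comparison up to 2 rises and 2 falls among called members with a mean log2 CPM of at least 0, or else the member of highest expression; every called integrin subunit, ERBB receptor and ligand; 5 genes per direction shared by both HER2 forms; and the 5 largest differences between the forms among genes called in opposite directions. The shared genes were ranked under the same limits as the 10 largest rises and falls. The opposite genes were ranked among protein-coding genes with a mean log2 CPM of at least 2, so genes of lower expression can differ more. The rule names 230 genes, not all of which are printed. MALAT1, NEAT1, COL1A2, COL3A1, PROM1, KRT78, ESRP1 and ESRP2 fall outside it and were chosen after values were seen. Main genes lie at these places: FN1 (ENSG00000115414.19, chromosome 2, 215360440 to 215436172), VCAN (ENSG00000038427.16, chromosome 5, 83471465 to 83582303), IL6 (ENSG00000136244.12, chromosome 7, 22725884 to 22732002), IL24 (ENSG00000162892.16, chromosome 1, 206897443 to 206904139), ITGA5 (ENSG00000161638.11, chromosome 12, 54395261 to 54419460) and ITGB8 (ENSG00000105855.10, chromosome 7, 20330702 to 20415754). Others are CLDN4 (ENSG00000189143.9, chromosome 7, 73799542 to 73832693), KLK7 (ENSG00000169035.12, chromosome 19, 50976482 to 50984099), VTCN1 (ENSG00000134258.17, chromosome 1, 117143587 to 117210960), IFI27 (ENSG00000165949.12, chromosome 14, 94104836 to 94116698), SERPINB2 (ENSG00000197632.9, chromosome 18, 63871692 to 63903890) and LAMA3 (ENSG00000053747.16, chromosome 18, 23689443 to 23956222).

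The fold changes of both HER2 forms use the same controls, so their correlation, covariance and overlap were set beside values simulated from unchanged groups with shared controls and beside the overlap of independent lists. The gene tests were tried on counts simulated for all 9 libraries, from the mean levels of the empty-vector group and the library sizes and spread of all groups (14080 genes in edgeR). Of 50 genes changed in HER2d16 at each size, edgeR recovered 25 at 1.2-fold, 41 at 1.5-fold, 39 at 2-fold and 49 at 4-fold, with 5 false calls. On the same data DESeq2 recovered 145 and limma-voom 154 of the 200 changed genes, against 154 in edgeR. In the real data 6717 genes were called with HER2d16, so the shares recovered need not carry over.

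Alternative settings of the gene tests, fixed at that point, were no filter except a total count above 0, a CPM of at least 1 in at least 3 libraries, RLE size factors, library size alone, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the 6 libraries compared, a test against a fold change of 1.5 (glmTreat), RSEM expected counts, and leaving out each of the 9 libraries. For the lists they were the estimated correlation, fry, library size alone, the block, and leaving out each library. Counts on both strands, libraries thinned to equal depth, and removal of trends with GC content and transcript length were chosen after seeing the data. A planned table of ERBB2 transcripts could not be made, since the RSEM tables are at gene level. Some genes are not reported here by name; they stay in the counts and the list tests. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.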

Results

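RNA-seq was made from MCF10A, a non-tumorigenic human mammary epithelial cell line, in which cells growing with serum stably expressed an empty vector, full-length HER2 (HER2WT), or HER2d16, the receptor form made by skipping of a single exon. Each group had 3 libraries, 9 in all. Reads assigned to genes ranged from 13407509 to 48892784 per library. Levels are counts-per-million values (CPM) as mean ± SD over the 3 libraries of a group. Log2 fold changes carry an approximate standard error, the absolute log2 fold change divided by the square root of its F statistic. For large changes of genes with few reads in a group, such as KLK7, it can be smaller than counting error alone. The first principal component, with 58.2% of the variance, placed the empty-vector libraries between -55.2 and -53.5 and the 6 HER2 libraries between 20.3 and 33.9. The next component, with 26.1%, placed HER2d16 between 28.1 and 29.95 and HER2WT between -36.03 and -31.7. Pairs of libraries within a group differed by 1.8 to 18.2 times the variance that counting alone gives. The labels do not say whether the replicates were separate cultures, so all p-values measure only the spread between these libraries.

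The receptor transcript itself separated the groups. ERBB2 (ENSG00000141736.13, chromosome 17, 39687914 to 39730426, on GRCh38), which encodes HER2, stood at 82.4, 87.4 and 101 CPM in the empty-vector libraries, at 939, 941 and 949.6 CPM with HER2WT, and at 1465, 1408 and 1502 CPM with HER2d16. It rose 10.4-fold with HER2WT (log2 fold change 3.39 ± 0.06, adjusted p = 6.4e-21) and 16.2-fold with HER2d16 (4.01 ± 0.06, adjusted p = 6.1e-22). The HER2d16 level was also 1.55 times that of HER2WT (0.63 ± 0.06, adjusted p = 8.0e-09). The HER2 lines thus differed in receptor transcript level as well as in receptor form, and the counts are per gene and do not tell the constructs apart.

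The comparison of HER2d16 with empty vector asks what the exon-skipped receptor does to mammary epithelial cells. HER2d16 cells carried more transcripts of the interstitial matrix and NF-kB lists and fewer of epithelial junctions (adjusted p = 6.5e-11, 0.0013 and 1.3e-21, and adjusted p = 0.051, 0.042 and 0.0085 with an estimated correlation). FN1, which encodes the integrin ligand fibronectin, rose from 215 ± 25.4 to 1465 ± 28.1 CPM (log2 fold change 2.76 ± 0.06, n = 3 libraries per group), and IL1B, an inflammatory cytokine, rose from 55.01 ± 0.102 to 714 ± 9.37 CPM (3.7 ± 0.05). CLDN4, a claudin of tight junctions, fell from 87.9 ± 8.82 to 1.12 ± 0.20 CPM (-6.32 ± 0.13), and KLK7, a serine protease of the epidermis, fell from 267 ± 9.23 to 0.545 ± 0.181 CPM (-8.99 ± 0.11). VTCN1, an immune checkpoint ligand, had 1 read in the 3 HER2d16 libraries against 1502 with empty vector, a ratio of 925 with a 95% counting interval of 166 to 36549. Such intervals, and the lower bounds given for genes with 0 reads in a group, cover counting error only.

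Of 14296 genes tested, 3314 rose and 3403 fell with HER2d16, 603 and 786 of them by over 2-fold. The largest rises included SAMSN1, an adaptor protein of lymphoid cells (from 0.665 ± 0.30 to 62.4 ± 1.78 CPM), ALOX5AP, which serves leukotriene synthesis (from 1.51 ± 0.272 to 39.8 ± 0.848 CPM), IL7R (from 2.96 ± 0.257 to 56.3 ± 2.34 CPM), CSF3, the granulocyte growth factor (from 14.4 ± 1.3 to 225 ± 7.83 CPM), and TGM2, a crosslinking transglutaminase (from 10.9 ± 1.3 to 137 ± 3.98 CPM). The largest falls included KLK5 (from 218 ± 20.01 to 1.34 ± 0.297 CPM), KLK10 (from 129 ± 15.2 to 0.625 ± 0.287 CPM), the transporter ATP13A4 (from 22.7 ± 0.443 to 0.101 ± 0.0216 CPM) and IGFL1 (from 76.1 ± 8.9 to 0.791 ± 0.147 CPM). Many changes were small, and a test against a fold change of 1.5 left 648 rises and 864 falls. Mitochondrially encoded genes, a sign of RNA quality, made up 2.69 ± 0.231% of the reads with HER2d16 against 1.53 ± 0.261% with empty vector. All 13 rose (median log2 fold change 0.82, adjusted p = 2.0e-05, adjusted p = 0.26 with an estimated correlation), MT-ND1 from 884 ± 151 to 1761 ± 149.7 CPM, and the nucleus-retained RNA MALAT1 rose as well (log2 fold change 0.77 ± 0.11, adjusted p = 1.5e-04).

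**Figure D1:**
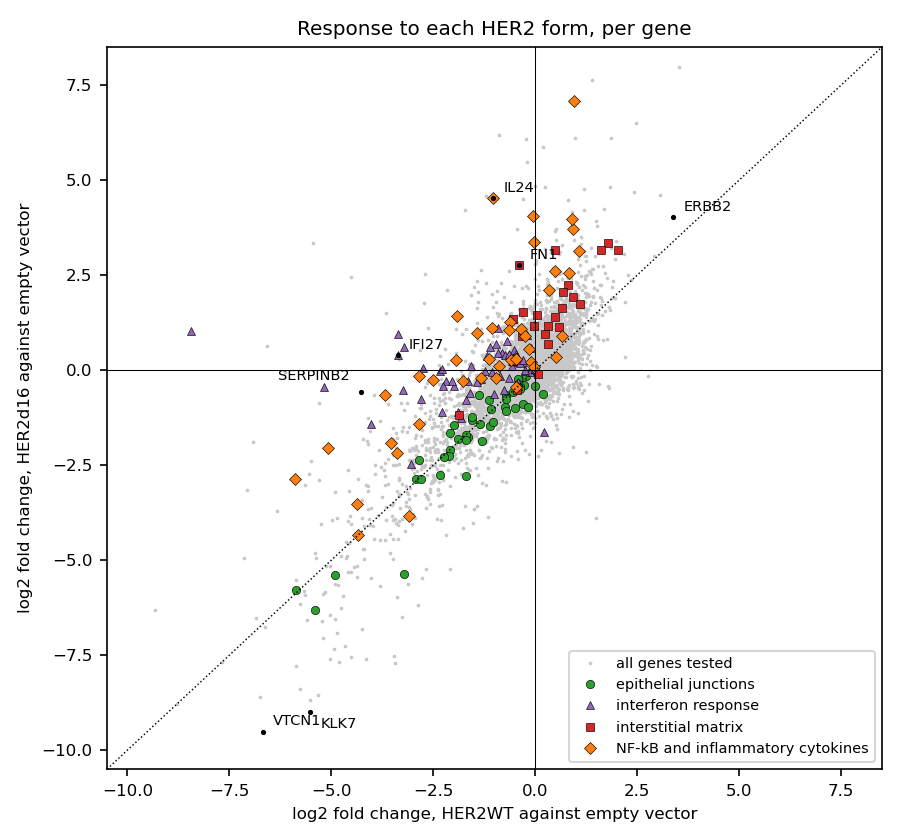
Log2 fold change of every tested gene with HER2WT (horizontal) and with HER2d16 (vertical) against empty vector, with 4 gene lists coloured, the dotted line marking equal change, and genes without reads in a group drawn at their fitted value, which is no bound. ERBB2 lies at 3.39 and 4.01, and interferon genes have a median of -0.99 with HER2WT and 0.01 with HER2d16.

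Integrin subunits, the receptors that bind cells to matrix and that the series title names, rose as a group with HER2d16. 13 of the 16 tested subunits rose and 2 fell (median log2 fold change 0.39, adjusted p = 5.1e-04, adjusted p = 0.042 with an estimated correlation). ITGA5, the alpha chain of the fibronectin receptor, rose from 97.1 ± 7.94 to 175 ± 10.6 CPM (0.85 ± 0.06, adjusted p = 1.2e-10), and the collagen receptor chain ITGA1 rose from 20.7 ± 1.71 to 55.9 ± 2.89 CPM (1.43 ± 0.07). The common beta chain ITGB1 rose from 1819 ± 126 to 2344 ± 42.8 CPM (0.37 ± 0.05). The leukocyte chain ITGB2 rose from 14.1 ± 1.57 to 33.7 ± 0.68 CPM (1.25 ± 0.08), and ITGA6, the hemidesmosome alpha chain, rose from 1022 ± 73.1 to 1686 ± 4.43 CPM (0.72 ± 0.05). ITGB8, which with ITGAV activates latent TGF-beta, fell from 474 ± 59.8 to 69.5 ± 1.61 CPM (-2.77 ± 0.08, adjusted p = 6.2e-15). Focal adhesion and integrin signalling genes did not pass as a group (median log2 fold change 0.04, adjusted p = 0.10), although 19 of 50 rose and 8 fell. The scaffold NEDD9 rose from 2.99 ± 0.316 to 9.54 ± 0.35 CPM and TNS3 from 39.2 ± 3.55 to 71.5 ± 3.39 CPM, and the tensin TNS1 fell from 8.4 ± 1.13 to 1.01 ± 0.281 CPM. The hemidesmosome and epidermal adhesion list had 7 of 11 higher and 2 lower (median log2 fold change 0.59, adjusted p = 0.017, adjusted p = 0.26 with an estimated correlation). The basement membrane list had 13 of 23 higher and 4 lower (14 and 5 adjusted over the list alone, median log2 fold change 0.34, adjusted p = 0.0031, adjusted p = 0.23 with an estimated correlation). The laminin chain LAMB3 rose by 1.15 ± 0.07, and the collagen IV chains COL4A1 and COL4A2 by 1.53 ± 0.05 and 1.28 ± 0.05. Among matrix proteases and their inhibitors 14 of 43 rose and 22 fell, and the list did not pass (16 and 23 adjusted over the list alone, median log2 fold change -0.23, adjusted p = 0.11). ADAMTS6 rose from 2.56 ± 0.178 to 11.7 ± 1.01 CPM and MMP19 from 1.08 ± 0.137 to 4.92 ± 0.147 CPM. In the same libraries mitochondrially encoded reads were 2.69% against 1.53%.

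Interstitial matrix genes rose in HER2d16 cells, 20 of 24 tested, with 2 lower (median log2 fold change 1.41, adjusted p = 6.5e-11, adjusted p = 0.051 with an estimated correlation). The proteoglycans VCAN and DCN rose from 28.9 ± 4.19 to 296 ± 9.52 CPM (3.34 ± 0.07) and from 23.1 ± 1.36 to 208 ± 9.998 CPM (3.16 ± 0.06). The short-chain collagen COL8A1 rose from 31.2 ± 1.35 to 279.7 ± 5.38 CPM, and the fibrillar collagen COL1A1 fell from 8.76 ± 1.32 to 3.79 ± 1.07 CPM (-1.18 ± 0.15). Mesenchymal and EMT regulators rose with them, 21 of 27, with 2 lower (median log2 fold change 0.77, adjusted p = 2.6e-09, adjusted p = 0.0085 with an estimated correlation). WNT5A, a non-canonical Wnt ligand, rose from 3.25 ± 0.148 to 19.5 ± 0.886 CPM. Markers of fibroblasts, read as signs of another cell type, had 4 of 7 tested higher and 3 lower, and did not pass (median log2 fold change 0.47, adjusted p = 0.18). 8 of the 15 markers also stand in other lists, DCN among them. The marker FAP, a membrane protease, rose from 51.05 ± 2.82 to 167 ± 6.69 CPM, and the abundant fibroblast collagens COL1A2 and COL3A1 stayed at 0.0142 and 0.0285 CPM, scaled by library size alone. Mitochondrially encoded reads moved with these lists, 2.69% against 1.53%.

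Epithelial junction genes fell as a group. 43 of the 45 tested fell (median log2 fold change -1.31, adjusted p = 1.3e-21, adjusted p = 0.0085 with an estimated correlation). Besides CLDN4, the epithelial transcription factor ELF3 fell from 98.1 ± 6.77 to 1.78 ± 0.384 CPM (-5.79 ± 0.10, adjusted p = 3.9e-21). Luminal mammary markers fell, 14 of 20, with 2 higher (median log2 fold change -1.21, adjusted p = 4.5e-06, adjusted p = 0.017 with an estimated correlation). EHF and XBP1, transcription factors of that list, rose by 0.37 ± 0.06 and 0.37 ± 0.05. Keratinocyte differentiation genes had 25 of 35 lower and 5 higher (median log2 fold change -1.87, adjusted p = 1.9e-06, adjusted p = 0.079 with an estimated correlation). The keratins KRT13 and KRT4 had 1 and 2 reads in HER2d16 libraries against 771 and 694, ratios of 475 (84.9 to 18773) and 214 (58.9 to 1768). The serpins SERPINB3 and SERPINB4 rose by 1.63 ± 0.12 and 1.78 ± 0.19. Keratins and these serpins have close paralogs, so their levels are uncertain. Basal mammary markers split, 14 of 27 higher and 12 lower, and were not called (median log2 fold change 0.18, adjusted p = 0.45). Their mean was -0.18 and the test direction upward. The membrane peptidase MME rose from 31.7 ± 2.24 to 88.5 ± 4.68 CPM, and the basal keratins KRT14 and KRT15 fell from 469 ± 66.1 to 84.1 ± 6.41 CPM and from 558 ± 61.5 to 36.9 ± 1.81 CPM. The medians of the luminal and keratinocyte lists were the same with PROM1 and KRT78, which had 0 reads with HER2d16, set at their bounds. Beside these falls mitochondrially encoded reads were 2.69% against 1.53%.

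ERBB receptors and ligands had 9 of 18 higher and 7 lower, and the list did not pass (median log2 fold change 0.19, adjusted p = 0.17). ERBB2, which the HER2 constructs add, is a member of this list and counted among the higher genes in every comparison. AREG and EREG, ligands of EGFR, rose from 312 ± 21.2 to 1901 ± 64.1 CPM (2.61 ± 0.05) and from 11.2 ± 1.28 to 70.3 ± 2.26 CPM (2.65 ± 0.07). NRG1 and HBEGF rose by 1.33 ± 0.11 and 0.89 ± 0.07, and TGFA, BTC, NRG2 and NRG4 fell by 0.61, 0.61, 1.16 and 0.52 on the log2 scale. ERBB3, the kinase-poor partner of HER2, fell from 43.1 ± 1.22 to 8.35 ± 0.348 CPM (-2.36 ± 0.08), and EGFR rose from 409 ± 36.00 to 577 ± 2.37 CPM (0.50 ± 0.05). Genes induced by MAPK signalling had 20 of 41 higher and 8 lower (median log2 fold change 0.15, adjusted p = 0.038, adjusted p = 0.15 with an estimated correlation). FOSL1 rose by 1.08 ± 0.10, while LIF and EMP1 fell by 2.19 and 2.1. That call ended without HER2d16 replicate 1 (adjusted p = 0.0503) or empty-vector replicate 1 (adjusted p = 0.079). FOXO targets, which PI3K and AKT repress, had 18 of 30 lower and 4 higher (median log2 fold change -0.30, adjusted p = 5.3e-04, adjusted p = 0.12 with an estimated correlation), TP53INP2 falling from 45.6 ± 4.01 to 13.3 ± 0.167 CPM and IRS1 rising from 4.0 ± 0.325 to 15.6 ± 0.746 CPM. Proliferation genes had 42 of 64 higher and 1 lower by small amounts (48 and 1 adjusted over the list alone, median log2 fold change 0.20, adjusted p = 6.3e-07, adjusted p = 0.063 with an estimated correlation), HJURP from 65.6 ± 3.27 to 91.3 ± 0.797 CPM. TGF-beta targets had 17 of 32 higher and 8 lower (median log2 fold change 0.26, adjusted p = 0.015, adjusted p = 0.063 with an estimated correlation). INHBA, a subunit of activin, rose from 26.4 ± 1.09 to 129 ± 5.12 CPM, and FST, which binds activin, fell from 57.5 ± 3.34 to 12.2 ± 0.963 CPM. YAP and TAZ targets had 16 of 28 higher and 6 lower (median log2 fold change 0.24, adjusted p = 0.012, adjusted p = 0.079 with an estimated correlation), with the receptor kinase AXL rising from 7.6 ± 0.536 to 38.2 ± 3.0 CPM and the matricellular gene CCN1 from 108 ± 3.04 to 273 ± 4.22 CPM. Beside these lists mitochondrially encoded reads were 2.69% against 1.53%, and MALAT1 rose by 0.77 ± 0.11.

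Inflammatory genes under NF-kB rose in HER2d16 cells, 25 of 42, with 10 lower (25 and 11 adjusted over the list alone, median log2 fold change 0.29, adjusted p = 0.0013, adjusted p = 0.042 with an estimated correlation). IL6 rose from 1.25 ± 0.276 to 21.4 ± 2.49 CPM (4.05 ± 0.14, adjusted p = 1.5e-16). IL24, a cytokine of the IL-10 family, rose from 1.03 ± 0.289 to 25.1 ± 0.401 CPM (4.53 ± 0.14), and the mitochondrial dismutase SOD2 rose from 340.0 ± 20.8 to 1475 ± 68.8 CPM (2.12 ± 0.06). CCL28, a mucosal chemokine, fell from 296 ± 26.4 to 14.7 ± 1.14 CPM, and IL1RN, the antagonist of IL-1, fell from 26.7 ± 0.432 to 1.88 ± 0.387 CPM. The interferon response split, with 23 of 60 higher and 20 lower (23 and 21 adjusted over the list alone, median log2 fold change 0.01, adjusted p = 0.81). Its mean was -0.05 and its test direction upward, with no call. GBP1 rose from 72.7 ± 2.9 to 157 ± 8.79 CPM and IFIT1 fell from 79.99 ± 2.91 to 14.4 ± 2.14 CPM. Glycolysis and hypoxia genes had 32 of 41 higher and 2 lower (35 and 2 adjusted over the list alone, median log2 fold change 0.41, adjusted p = 4.1e-10, adjusted p = 0.068 with an estimated correlation), with the glucose transporter SLC2A3 rising from 0.653 ± 0.259 to 5.93 ± 0.174 CPM and the vasodilator peptide ADM from 8.24 ± 0.116 to 43.1 ± 1.6 CPM. MALAT1 and NEAT1 rose in the same comparison, by 0.77 ± 0.11 and 0.69 ± 0.16, and mitochondrially encoded reads were 2.69% against 1.53%. Among the 29 lists 13 were called higher and 8 lower, and 5 of these calls held with an estimated correlation. The counts adjusted over the list alone equalled those over all genes for 20 of the 29 lists.

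**Figure D2:**
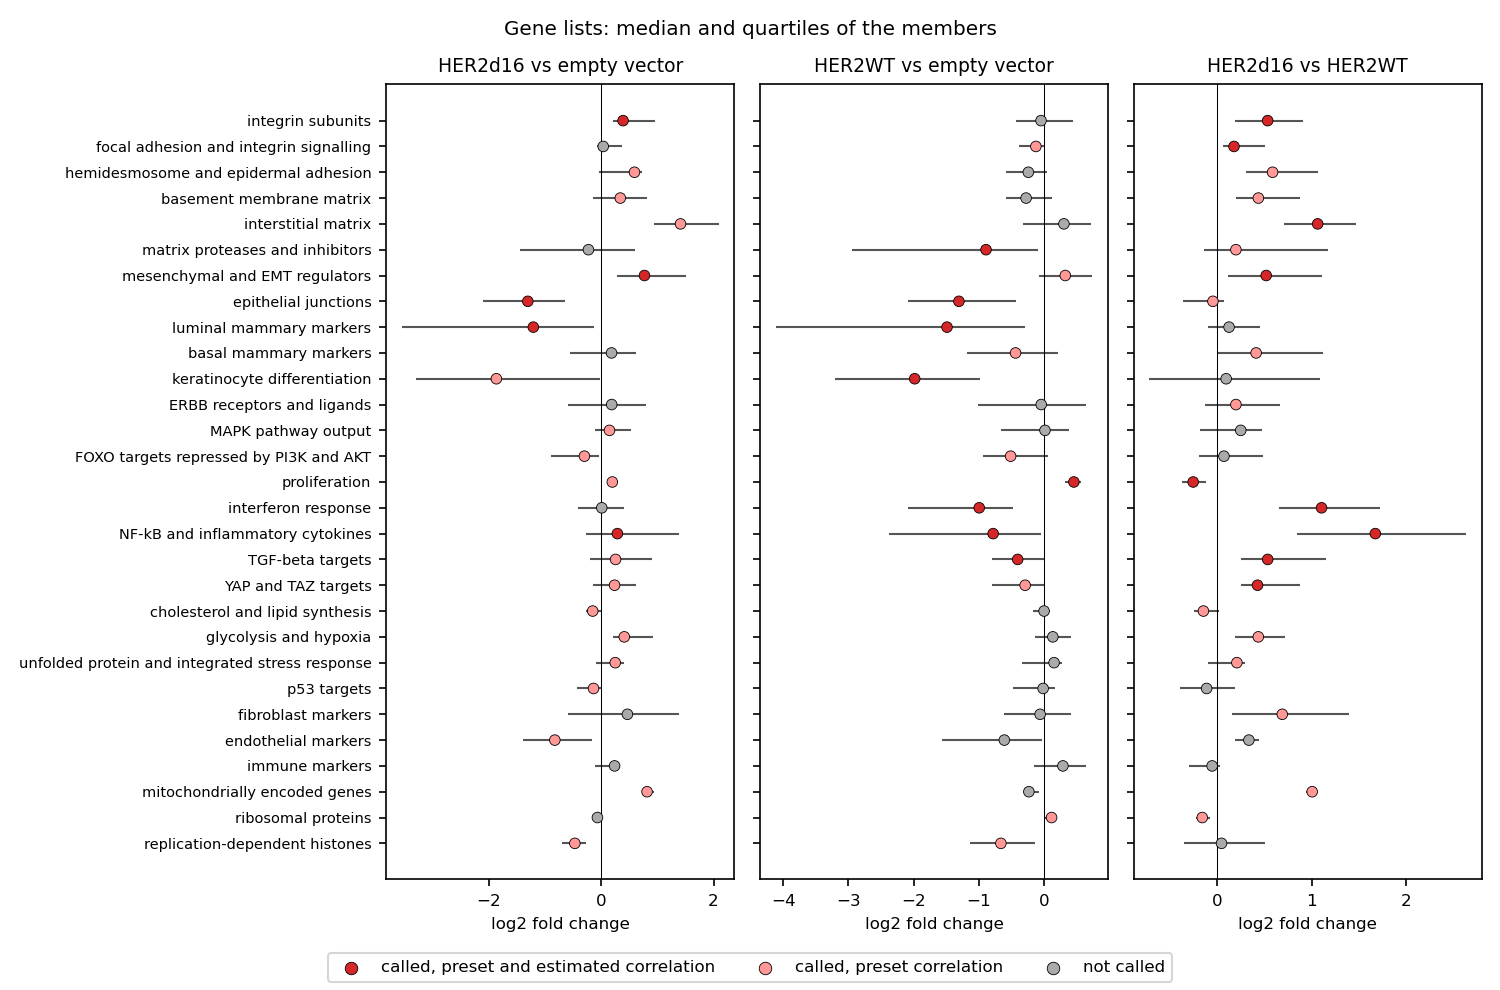
Median log2 fold change (points) and quartiles (lines) of the 29 gene lists in the 3 comparisons, in red where called with both the preset and the estimated correlation, pink where called with the preset one alone, and grey where not called. Epithelial junctions lie at -1.31 with HER2d16 and -1.3 with HER2WT against empty vector, and NF-kB genes at 1.67 in HER2d16 against HER2WT.

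The comparison of HER2WT with empty vector asks what the full-length receptor does in the same cells. HER2WT cells lost transcripts of epithelial junctions, keratinocyte differentiation, the interferon response and inflammation, and gained transcripts of cell division. IFI27, an interferon-induced gene, fell from 15.4 ± 1.48 to 1.42 ± 0.372 CPM (log2 fold change -3.36 ± 0.14, n = 3 libraries per group), CLDN4 fell from 87.9 ± 8.82 to 2.17 ± 0.391 CPM (-5.4 ± 0.11), and LCN2, an iron-binding protein of inflamed epithelium, fell from 73.9 ± 4.88 to 3.54 ± 0.227 CPM (-4.36 ± 0.09). The DNA clamp PCNA rose from 184 ± 13.9 to 306 ± 7.72 CPM (0.73 ± 0.05), and the matrix genes VCAN and COL8A1 rose from 28.9 ± 4.19 to 100.1 ± 2.3 CPM (1.78 ± 0.07) and from 31.2 ± 1.35 to 128 ± 7.44 CPM (2.04 ± 0.06). PCNA lies in a stretch of chromosome 20 whose 90 genes had a median log2 fold change of 0.29 with HER2WT. Part of its rise may belong to that stretch.

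With HER2WT 3764 genes rose and 4114 fell, 215 and 1052 of them by over 2-fold, so the larger changes were mostly falls. The test against a fold change of 1.5 left 245 rises and 1189 falls. Besides ERBB2, the largest rises included SAMSN1 (from 0.665 ± 0.30 to 3.79 ± 0.348 CPM), AXL (from 7.6 ± 0.536 to 27.8 ± 2.45 CPM), the aldehyde oxidase AOX1 (from 23.8 ± 1.06 to 75.3 ± 1.83 CPM), the actin bundler LCP1 (from 47.2 ± 0.689 to 136 ± 1.49 CPM) and RUNX2, a bone transcription factor (from 3.17 ± 0.675 to 9.93 ± 0.482 CPM). The largest falls included VTCN1 (from 15.3 ± 1.14 to 0.148 ± 0.0948 CPM), ATP13A4 (from 22.7 ± 0.443 to 0.397 ± 0.0632 CPM), ELF3 (from 98.1 ± 6.77 to 1.7 ± 0.0573 CPM) and KLK7 (from 267 ± 9.23 to 5.95 ± 0.667 CPM). Mitochondrially encoded reads made up 1.37 ± 0.18%, and no shift of the 13 genes was called (median log2 fold change -0.23, adjusted p = 0.38). Without empty-vector replicate 2 that list was called lower (adjusted p = 0.040). MALAT1 fell (log2 fold change -0.30 ± 0.11, adjusted p = 0.034). Ribosomal protein genes, another sign of RNA quality, had 34 of 77 higher and 1 lower (32 and 1 adjusted over the list alone, median log2 fold change 0.12, adjusted p = 0.0015, adjusted p = 0.57 with an estimated correlation).

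Integrin subunits went both ways with HER2WT, 8 higher and 8 lower of 16 (median log2 fold change -0.04, adjusted p = 0.97). ITGA6 rose from 1022 ± 73.1 to 1389 ± 42.7 CPM (0.44 ± 0.05), and ITGA10 and ITGA1 rose by 0.96 ± 0.07 and 0.54 ± 0.07. ITGB8 fell from 474 ± 59.8 to 74.7 ± 6.63 CPM (-2.66 ± 0.08), and ITGB6, ITGA3, ITGA5 and ITGB1 fell by 0.70, 0.44, 0.30 and 0.27 on the log2 scale. Focal adhesion and integrin signalling genes fell, 25 of 50, with 8 higher (median log2 fold change -0.12, adjusted p = 0.023, adjusted p = 0.15 with an estimated correlation). TNS1 fell from 8.4 ± 1.13 to 0.627 ± 0.109 CPM and TNS3 rose from 39.2 ± 3.55 to 75.7 ± 2.95 CPM. Hemidesmosome genes had 2 of 11 higher and 6 lower (median log2 fold change -0.24, adjusted p = 0.20). Basement membrane genes had 5 of 23 higher and 10 lower (median log2 fold change -0.27, adjusted p = 0.54). The laminin chain LAMA3 fell from 1516 ± 106 to 896 ± 14.6 CPM, and COL4A1 rose from 28.8 ± 0.574 to 61.3 ± 1.62 CPM. Matrix proteases and inhibitors fell, 28 of 43, with 7 higher (8 and 28 adjusted over the list alone, median log2 fold change -0.89, adjusted p = 1.9e-06, adjusted p = 0.034 with an estimated correlation). The macrophage elastase MMP12 had 0 reads in the HER2WT libraries against 298, at least 83.3-fold lower. ADAM12 rose from 15.1 ± 1.26 to 37.8 ± 1.02 CPM. The list's median was the same with MMP12 at its bound. In these libraries MALAT1 changed by -0.30 ± 0.11.

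Mesenchymal and EMT regulators had 16 of 27 higher and 5 lower with HER2WT (median log2 fold change 0.33, adjusted p = 0.020, adjusted p = 0.10 with an estimated correlation). The transcription factor FOXC2 rose from 3.7 ± 0.16 to 9.08 ± 0.493 CPM, while TGFB2 fell from 11.3 ± 0.894 to 4.61 ± 0.423 CPM and TAGLN, an actin-binding protein of smooth muscle, fell from 196 ± 20.8 to 84.03 ± 5.32 CPM. Interstitial matrix genes had 12 of 24 higher and 7 lower and were not called (median log2 fold change 0.31, adjusted p = 0.092). Without empty-vector replicate 2 they were (adjusted p = 0.034). COL1A1 and SPARC fell by 1.87 and 0.56 on the log2 scale, and DCN rose from 23.1 ± 1.36 to 70.6 ± 1.95 CPM. Fibroblast markers had 3 of 7 higher and 3 lower (median log2 fold change -0.06, adjusted p = 0.96), with a median below 0 and a test direction above it. PDPN, a mucin-type membrane protein, rose from 25.3 ± 1.79 to 41.4 ± 1.8 CPM and MFAP5 fell from 22.5 ± 0.704 to 13.1 ± 1.17 CPM. In the same comparison MALAT1 fell (-0.30 ± 0.11).

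Epithelial junctions fell, 40 of 45, with 1 higher (median log2 fold change -1.3, adjusted p = 5.5e-16, adjusted p = 0.011 with an estimated correlation). The adhesion molecule EPCAM was the 1 that rose, from 149 ± 6.4 to 171 ± 4.31 CPM. Luminal markers fell as well, 15 of 20, with 3 higher (median log2 fold change -1.49, adjusted p = 5.2e-06, adjusted p = 0.013 with an estimated correlation), and the milk protein LTF rose from 0.552 ± 0.26 to 3.3 ± 0.246 CPM. Keratinocyte differentiation genes fell, 31 of 35, with 1 higher (1 and 32 adjusted over the list alone, median log2 fold change -1.98, adjusted p = 4.0e-12, adjusted p = 0.034 with an estimated correlation), KRT13 from 7.8 ± 1.28 to 0.166 ± 0.086 CPM. Basal markers had 16 of 27 lower and 10 higher (median log2 fold change -0.43, adjusted p = 0.039, adjusted p = 0.38 with an estimated correlation), a call that ended without empty-vector replicate 3 (adjusted p = 0.057) and with the replicate number as a block (adjusted p = 0.0502). KRT14 fell from 469 ± 66.1 to 66.9 ± 2.76 CPM, the chaperone CRYAB fell from 7.15 ± 0.533 to 0.611 ± 0.22 CPM, and MME rose from 31.7 ± 2.24 to 62.8 ± 1.18 CPM. Beside these falls MALAT1 fell by 0.30.

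Proliferation genes rose with HER2WT, 56 of 64 (57 and 0 adjusted over the list alone, median log2 fold change 0.46, adjusted p = 3.3e-16, adjusted p = 0.016 with an estimated correlation). CKS2, a cyclin-dependent kinase subunit, rose from 76.3 ± 3.03 to 127 ± 5.11 CPM (0.73 ± 0.05, adjusted p = 9.3e-11). The ERBB ligands AREG and EREG rose from 312 ± 21.2 to 774 ± 13.1 CPM (1.31 ± 0.05) and from 11.2 ± 1.28 to 29.96 ± 0.517 CPM (1.42 ± 0.08). HBEGF, TGFA and BTC fell by 0.95, 1.14 and 1.54 on the log2 scale, and ERBB3 fell from 43.1 ± 1.22 to 9.41 ± 0.956 CPM. The list had 7 of 18 higher, ERBB2 itself included, and 8 lower, with a median of -0.04, a mean of -0.01 and an upward test direction that did not pass (adjusted p = 0.91). MAPK output had 18 of 41 higher and 15 lower (18 and 16 adjusted over the list alone), a median of 0.02, a mean of -0.16 and an upward test direction that did not pass (adjusted p = 0.75). The phosphatase DUSP6, a feedback inhibitor of ERK, rose from 99.1 ± 1.89 to 189 ± 5.96 CPM, ETV1 rose from 25.4 ± 2.98 to 42.9 ± 1.09 CPM, and LIF fell from 155 ± 10.8 to 15.2 ± 1.78 CPM. FOXO targets fell, 21 of 30, with 7 higher (8 and 21 adjusted over the list alone, median log2 fold change -0.51, adjusted p = 6.6e-04, adjusted p = 0.15 with an estimated correlation), TP53INP2 from 45.6 ± 4.01 to 6.15 ± 0.957 CPM. TGF-beta targets fell, 20 of 32, with 6 higher (7 and 20 adjusted over the list alone, median log2 fold change -0.40, adjusted p = 0.0029, adjusted p = 0.034 with an estimated correlation). BAMBI and FST, which restrain the pathway, fell by 2.07 and 2.7, and TGFBI and SMAD7 rose by 0.49 ± 0.05 and 0.58 ± 0.14. YAP and TAZ targets fell, 16 of 28, with 5 higher (5 and 17 adjusted over the list alone, median log2 fold change -0.29, adjusted p = 0.016, adjusted p = 0.10 with an estimated correlation), IGFBP3 from 30.4 ± 1.7 to 4.25 ± 0.556 CPM, while AXL rose. Beside these lists MALAT1 changed by -0.30 ± 0.11, and ribosomal proteins had a median of 0.12.

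The interferon response fell with HER2WT, 53 of 60 genes (median log2 fold change -0.99, adjusted p = 1.1e-18, adjusted p = 0.010 with an estimated correlation). RSAD2, an antiviral enzyme, fell from 11.1 ± 0.329 to 0.621 ± 0.233 CPM (-4.02 ± 0.17), and OAS2, which makes oligoadenylates in response to viral RNA, fell from 11.8 ± 0.699 to 1.29 ± 0.196 CPM (-3.23 ± 0.15). The pro-apoptotic gene XAF1 had 0 reads against 159, at least 44.4-fold lower. The median was the same with XAF1 at its bound. Inflammatory genes under NF-kB fell, 29 of 42, with 8 higher (median log2 fold change -0.78, adjusted p = 2.5e-05, adjusted p = 0.013 with an estimated correlation). CCL28 fell from 296 ± 26.4 to 14.6 ± 0.697 CPM, and IL1B and the chemokine CCL20 rose from 55.01 ± 0.102 to 105 ± 1.18 CPM and from 7.43 ± 0.395 to 15.4 ± 1.23 CPM. Glycolysis and hypoxia genes had 21 of 41 higher and 10 lower and were not called (median log2 fold change 0.14, adjusted p = 0.074). They were called without empty-vector replicate 3 (adjusted p = 0.029) and, in a test chosen after seeing the data, once trends with GC content and length were removed (adjusted p = 0.047). EGLN3, an oxygen-sensing hydroxylase, rose from 6.57 ± 0.0473 to 11.5 ± 1.31 CPM. MALAT1 fell in the same comparison, and ribosomal proteins had a median of 0.12. Of the 29 lists 3 were called higher and 12 lower, 8 of them also with an estimated correlation, and 18 had equal counts adjusted over the list alone.

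The direct comparison of HER2d16 with HER2WT asks how the exon-skipped form differs from the full-length receptor, and its tests are the tests of a difference between the forms. HER2d16 cells had more inflammatory, interferon, interstitial matrix and integrin transcripts and fewer proliferation transcripts than HER2WT cells. IL24 was 25.1 ± 0.401 against 0.496 ± 0.122 CPM (log2 fold change 5.56 ± 0.16, n = 3 libraries per group), FN1 1465 ± 28.1 against 164 ± 2.08 CPM (3.16 ± 0.07), and OAS2 17.7 ± 2.81 against 1.29 ± 0.196 CPM (3.83 ± 0.15). SERPINB2, the plasminogen activator inhibitor of inflamed epithelium, was 333 ± 27.3 against 26.1 ± 1.01 CPM (3.68 ± 0.07). KLK7 was lower in HER2d16, 0.545 ± 0.181 against 5.95 ± 0.667 CPM (-3.46 ± 0.18), as was SULT1E1, the oestrogen sulfotransferase, 1.38 ± 0.505 against 14.9 ± 0.531 CPM (-3.4 ± 0.17).

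Between the HER2 forms 3315 genes were higher in HER2d16 and 2888 lower, 681 and 175 of them by over 2-fold. Against a fold change of 1.5 there were 636 higher and 142 lower. Higher genes made up 53.4% of the calls, and 42.96% when libraries were scaled by their size alone. The largest rises included SAMSN1 (62.4 ± 1.78 against 3.79 ± 0.348 CPM), IFI27 (20.2 ± 2.31 against 1.42 ± 0.372 CPM), CTSS, a lysosomal protease (25.3 ± 0.79 against 1.99 ± 0.208 CPM), ALOX5AP (39.8 ± 0.848 against 3.31 ± 0.0783 CPM) and the chemokine CXCL3 (40.1 ± 2.27 against 3.72 ± 0.276 CPM), which shares sequence with other CXCL genes. The largest falls included MAP2, a microtubule protein of neurons (2.09 ± 0.196 against 18.2 ± 0.447 CPM), A2ML1, a protease inhibitor (0.526 ± 0.0383 against 3.24 ± 0.655 CPM), and KLK10 (0.625 ± 0.287 against 4.64 ± 0.45 CPM). All 13 mitochondrially encoded genes were higher in HER2d16, with 2.69 ± 0.231% of reads against 1.37 ± 0.18% (median log2 fold change 1.0, adjusted p = 9.8e-07, adjusted p = 0.22 with an estimated correlation), MT-ND2 1493 ± 140.5 against 651 ± 78.95 CPM. MALAT1 and NEAT1, both retained in the nucleus, were higher too (log2 fold change 1.08 ± 0.11 and 0.84 ± 0.16, adjusted p = 1.8e-05 and 0.0044).

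Integrin subunits were higher in HER2d16 than in HER2WT, 11 of 16, with 1 lower (12 and 1 adjusted over the list alone, median log2 fold change 0.53, adjusted p = 3.7e-04, adjusted p = 0.028 with an estimated correlation). ITGA5 stood at 175 ± 10.6 against 78.8 ± 4.19 CPM (1.15 ± 0.06, adjusted p = 1.9e-12), and ITGB6, which activates latent TGF-beta, at 225 ± 4.24 against 115 ± 7.32 CPM (0.96 ± 0.06). ITGB1 was at 2344 ± 42.8 against 1512 ± 45.8 CPM (0.63 ± 0.05), and ITGA3, a laminin receptor chain, at 453 ± 10.9 against 299 ± 5.65 CPM (0.60 ± 0.06). ITGA10 was the lower one, 18.1 ± 1.05 against 29.97 ± 1.04 CPM (-0.73 ± 0.07). ITGB3, a vitronectin receptor chain, had 65 reads against 2, a ratio of 44.3 (11.8 to 373). Focal adhesion and integrin signalling genes were higher too, 27 of 50, with 1 lower (31 and 1 adjusted over the list alone, median log2 fold change 0.18, adjusted p = 2.4e-06, adjusted p = 0.027 with an estimated correlation). NEDD9 was 9.54 ± 0.35 against 1.48 ± 0.151 CPM, TGFB1I1, a paxillin relative, 10.4 ± 0.381 against 3.94 ± 0.284 CPM, while the SRC-family kinase YES1 was lower, 272 ± 1.91 against 317 ± 1.26 CPM. Hemidesmosome genes had 9 of 11 higher and 1 lower (median log2 fold change 0.58, adjusted p = 1.9e-04, adjusted p = 0.11 with an estimated correlation). Basement membrane genes had 15 of 23 higher and 1 lower (17 and 1 adjusted over the list alone, median log2 fold change 0.43, adjusted p = 2.8e-05, adjusted p = 0.11 with an estimated correlation). LAMA3 was 2373 ± 60.7 against 896 ± 14.6 CPM (1.41 ± 0.05) and LAMB3 845 ± 14.6 against 316 ± 12.2 CPM (1.42 ± 0.07). Matrix proteases and inhibitors had 20 of 43 higher and 9 lower (21 and 9 adjusted over the list alone, median log2 fold change 0.20, adjusted p = 0.0020, adjusted p = 0.11 with an estimated correlation), the gelatinase MMP9 at 1.71 ± 0.125 against 0.302 ± 0.251 CPM. In the same comparison ERBB2 itself was 1.55 times higher and mitochondrially encoded reads were 2.69% against 1.37%.

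**Figure D3:**
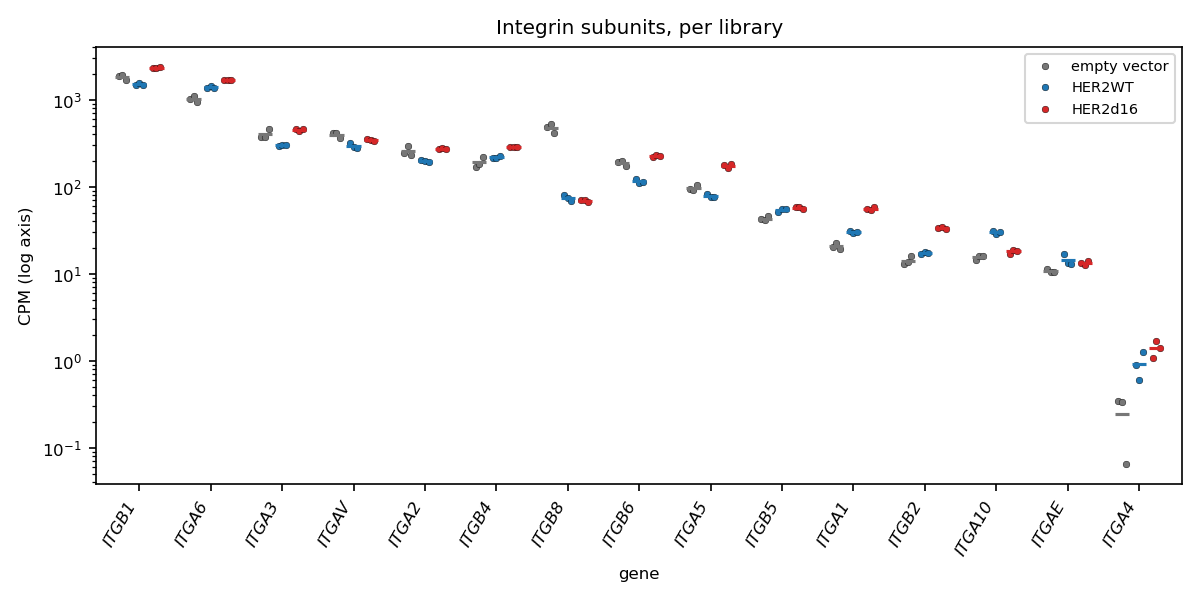
CPM on a log axis of the 15 integrin subunits with reads in every library, with points for libraries, a line at each group's mean, and colours for the 3 groups. ITGA5 averages 97.1 with empty vector, 78.8 with HER2WT and 175 with HER2d16, and ITGB8 averages 474, 74.7 and 69.5.

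Interstitial matrix genes were higher in HER2d16, 21 of 24 (median log2 fold change 1.06, adjusted p = 1.0e-11, adjusted p = 0.030 with an estimated correlation). COL6A3, a chain of microfibrillar collagen, was 9.8 ± 0.946 against 1.51 ± 0.111 CPM. Mesenchymal and EMT regulators were higher, 19 of 27, with 3 lower (median log2 fold change 0.52, adjusted p = 9.8e-07, adjusted p = 0.0099 with an estimated correlation). The calcium-binding protein S100A4 was lower (-0.62 ± 0.07). Fibroblast markers had 5 of 7 higher and 1 lower (median log2 fold change 0.69, adjusted p = 0.017, adjusted p = 0.094 with an estimated correlation), DCN 208 ± 9.998 against 70.6 ± 1.95 CPM and FAP 167 ± 6.69 against 56.2 ± 0.999 CPM. Epithelial junctions had 6 of 45 higher and 15 lower (median log2 fold change -0.05, adjusted p = 0.049, adjusted p = 0.22 with an estimated correlation). This call ended with scaling by library size alone (adjusted p = 0.052) and without HER2WT replicate 3, HER2d16 replicate 2, or empty-vector replicate 1 or 3 (adjusted p = 0.0503, 0.075, 0.053 and 0.075). PPL, a desmosome linker, was 22.3 ± 1.11 against 46.7 ± 1.23 CPM, and CLDN1 239.7 ± 3.28 against 145 ± 2.97 CPM. Luminal markers had 8 of 20 higher and 3 lower, a median of 0.12, a mean of -0.10 and an upward test direction that did not pass (adjusted p = 0.27). With PROM1, which had 0 reads with HER2d16, at its bound, the median was 0.18 and the mean 0.06. The mucin MUC1 was 99.9 ± 2.19 against 36.6 ± 0.915 CPM and KRT8 281 ± 7.3 against 141 ± 5.48 CPM. Basal markers had 17 of 27 higher and 3 lower (median log2 fold change 0.41, adjusted p = 1.3e-04, adjusted p = 0.11 with an estimated correlation), KRT17 903 ± 46.7 against 253 ± 18.9 CPM and KRT15 36.9 ± 1.81 against 105 ± 5.3 CPM. Keratinocyte genes had 12 of 35 higher and 9 lower (12 and 12 adjusted over the list alone, median log2 fold change 0.09, adjusted p = 0.28). The medians of the keratinocyte and protease lists were the same with KRT78 and MMP12, which had 0 reads in a group, at their bounds. In the same comparison mitochondrially encoded reads were 2.69% against 1.37%, and MALAT1 was higher (1.08 ± 0.11).

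Inflammatory genes under NF-kB showed the largest median of the 29 lists between the forms, with 37 of 42 higher and 1 lower (38 and 1 adjusted over the list alone, median log2 fold change 1.67, adjusted p = 4.7e-20, adjusted p = 8.6e-04 with an estimated correlation). IL6 was 21.4 ± 2.49 against 1.23 ± 0.0705 CPM (4.11 ± 0.14, adjusted p = 8.6e-16) and SOD2 1475 ± 68.8 against 428 ± 21.6 CPM (1.78 ± 0.06). IL1RN was lower, 1.88 ± 0.387 against 3.15 ± 0.198 CPM. Interferon genes were higher, 54 of 60, with 1 lower (median log2 fold change 1.1, adjusted p = 5.3e-24, adjusted p = 0.0026 with an estimated correlation). CXCL10, a chemokine for T cells, was 6.1 ± 0.424 against 0.253 ± 0.156 CPM, and XAF1 had 200 reads against 0, at least 90.8-fold higher. The median was the same with XAF1 at its bound. TGF-beta targets were higher, 24 of 32, with 1 lower (median log2 fold change 0.53, adjusted p = 6.3e-10, adjusted p = 0.0030 with an estimated correlation), INHBA 129 ± 5.12 against 14.5 ± 0.773 CPM (3.13 ± 0.06). Targets of YAP and TAZ were higher, 24 of 28, with 1 lower (median log2 fold change 0.42, adjusted p = 3.7e-09, adjusted p = 0.0070 with an estimated correlation). IGFBP3 was 43.6 ± 3.91 against 4.25 ± 0.556 CPM (3.34 ± 0.10) and CCN1 was 273 ± 4.22 against 74.3 ± 3.04 CPM (1.88 ± 0.05). Proliferation genes were lower in HER2d16, 44 of 64, with 1 higher (1 and 46 adjusted over the list alone, median log2 fold change -0.26, adjusted p = 3.5e-11, adjusted p = 0.028 with an estimated correlation). The mitotic cyclin CCNB2 was 98.8 ± 1.73 against 147 ± 4.37 CPM and the S-phase regulator E2F1, the higher one, 19.9 ± 0.768 against 15.5 ± 0.0567 CPM. Glycolysis and hypoxia genes had 33 of 41 higher and 1 lower (median log2 fold change 0.43, adjusted p = 2.5e-09, adjusted p = 0.093 with an estimated correlation), ADM 43.1 ± 1.6 against 9.95 ± 0.365 CPM. Signs of RNA quality moved in the same comparison. Mitochondrially encoded genes were higher, 13 of 13 (median log2 fold change 1.0, adjusted p = 9.8e-07, adjusted p = 0.22 with an estimated correlation), MALAT1 and NEAT1 were higher by 1.08 ± 0.11 and 0.84 ± 0.16, and ribosomal protein genes were lower, 43 of 77, with 1 higher (1 and 45 adjusted over the list alone, median log2 fold change -0.16, adjusted p = 4.0e-08, adjusted p = 0.22 with an estimated correlation).

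The ERBB list had 8 of 18 higher and 3 lower in HER2d16 (9 and 3 adjusted over the list alone, median log2 fold change 0.20, adjusted p = 0.045, adjusted p = 0.24 with an estimated correlation), a call that ended without HER2WT replicate 2 (adjusted p = 0.055) or HER2d16 replicate 3 (adjusted p = 0.063). ERBB2, which the constructs add, was among the higher genes and entered that test, and the list was not tested without it. The EGFR ligands HBEGF, AREG and EREG were higher by 1.84 ± 0.07, 1.3 ± 0.05 and 1.23 ± 0.07, and LRIG1, which restrains ERBB receptors, was lower (-0.55 ± 0.08). MAPK output had 19 of 41 higher and 10 lower (median log2 fold change 0.25, adjusted p = 0.10), with the feedback inhibitors SPRED3 higher (1.85 ± 0.17) and SPRY2 lower (-0.55 ± 0.07). FOXO targets had 12 of 30 higher and 8 lower (median log2 fold change 0.07, adjusted p = 0.28). The ubiquitin ligase FBXO32 was 47.3 ± 2.2 against 18.6 ± 1.04 CPM and the sestrin SESN3 4.33 ± 0.651 against 10.4 ± 0.841 CPM. Beside these lists mitochondrially encoded reads were 2.69% against 1.37%. Of the 29 lists 17 were called higher and 4 lower, 9 also with an estimated correlation, and 18 had equal counts adjusted over the list alone.

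**Figure D4:**
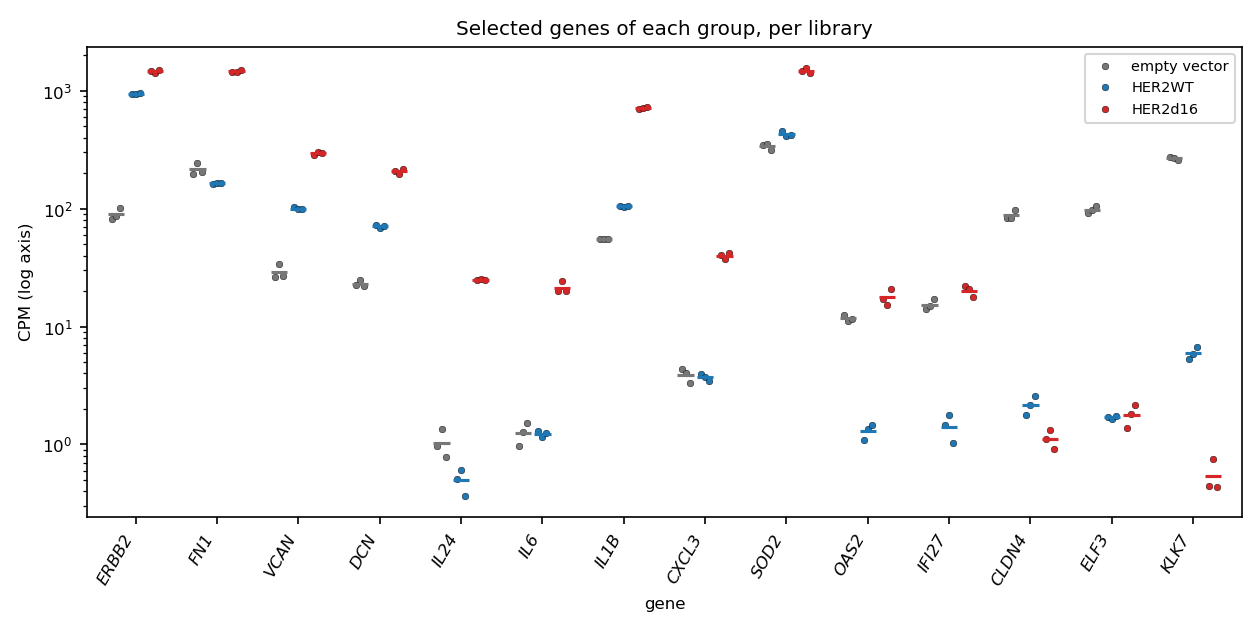
CPM on a log axis of 14 named genes in the 9 libraries, with points for libraries, a line at each group's mean, and colours for the 3 groups. FN1 averages 215 with empty vector, 164 with HER2WT and 1465 with HER2d16, and CLDN4 averages 87.9, 2.17 and 1.12.

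Set side by side, the responses to the HER2 forms shared the loss of epithelial genes and parted for part of the interferon and inflammatory genes. Against empty vector 1964 genes were higher and 2469 lower in both HER2 groups, and 399 genes moved in opposite directions, 273 up with HER2d16 and down with HER2WT and 126 the reverse. All 399 opposite genes passed the direct test between the forms, which opposite calls against the same controls in the same fit made all but certain. The interferon list held 21 opposite genes and the NF-kB list 13, all higher with HER2d16. Other members moved alike: 19 of the 60 interferon genes fell with both forms, and of the 42 NF-kB genes 8 rose and 10 fell with both. Of the 45 junction genes 40 fell with both forms and 1 was opposite. Among the opposite genes CTSS stood at 20.7 ± 2.02 CPM with empty vector, 1.99 ± 0.208 with HER2WT and 25.3 ± 0.79 with HER2d16. Fold changes against empty vector correlated across genes, which are not independent replicates (Pearson 0.734, Spearman 0.621), where unchanged groups simulated against the same controls gave 0.451 and 0.42 over 20 simulations. The covariance was 0.474 against a simulated 0.0114, a difference of 0.462. Signs were equal for 72.6% of genes (simulated 65.6%). Independent lists of these sizes would share 873 higher and 979 lower genes, and the simulated comparisons shared 0.15 and 0.050. The 3 controls are too few to give each comparison at least 2 of its own, so part of the excess of the correlations, of equal signs and of shared calls may come from the shared controls. A difference of the empty-vector line from both HER2 lines would be shared too. Stretches of chromosome 20 were picked for their shift in both comparisons. A stretch of 90 genes had medians of 0.26 with HER2d16 and 0.29 with HER2WT, and another of 60 genes -0.17 and -0.20. Between the forms these medians were -0.02 and 0.02. Responses to HER2 cannot be told apart from such a difference here.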

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

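The tests of fibroblast collagens, of chromosome windows, and of the number of opposite genes were chosen only after the results they address were seen. Responses to the HER2 forms differed in the direct test of HER2d16 against HER2WT for the following lists and genes. The median log2 fold change between the forms was 0.53 for integrin subunits, 0.18 for focal adhesion and integrin signalling, 0.53 for TGF-beta targets and 0.42 for YAP and TAZ targets. It was 1.67 for inflammatory genes under NF-kB, 1.1 for the interferon response and 1.0 for mitochondrially encoded genes, whose call ended with an estimated correlation (adjusted p = 0.22). Among genes that moved in opposite directions against empty vector, IL24 differed by 5.56, OAS2 by 3.83, IFI27 by 3.75, CTSS by 3.63 and SULT1E1 by -3.4 on the log2 scale. In all 399 genes were called in opposite directions.

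Mitochondrially encoded transcripts were higher in HER2d16 than in HER2WT and empty vector, by medians of 1.0 and 0.82, and both calls ended with an estimated correlation (adjusted p = 0.22 and 0.26). The tables argue against a joint rise of the whole respiratory chain: its 74 nuclear-encoded genes had a median of -0.14 against empty vector (95% bootstrap interval -0.17 to -0.08) and -0.13 against HER2WT. Loss of cytoplasmic RNA from damaged cells before extraction may account for it, since MALAT1 and NEAT1, which stay in the nucleus, rose as well, MALAT1 by 1.08 against HER2WT, in a test that could have come out the other way. A greater output of mitochondrial transcription in HER2d16 cells is a biological explanation that was not tested and stays open.

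Epithelial junction genes were lower in both HER2 groups than in empty vector. A trend with GC content or transcript length is argued against as the whole cause, since the median, -1.3 with HER2WT, was -1.17 (95% bootstrap interval -1.56 to -0.72) after its removal and -1.33 with HER2d16. Fibroblasts in place of epithelial cells are argued against, since COL1A1, among their most abundant transcripts, changed by -1.18 with HER2d16, from 8.76 to 3.79 CPM, and stood at 2.35 CPM with HER2WT. A difference in history between the empty-vector line and the HER2 lines stays open. In both HER2 groups 7 overlapping windows of 50 neighbouring genes, all on chromosome 20, shifted beyond shuffled gene order. Only 2 of the 45 junction genes lie on that chromosome. That count does not weigh against a difference in history, which need not be confined to 1 chromosome. A response to HER2 signalling is the biological explanation that the design names, and since the labels name no independent lines of a construct, it cannot be told apart from such a history.

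The 399 genes that moved in opposite directions with HER2d16 and HER2WT were weighed against the higher ERBB2 level of HER2d16. A response that only grows with the ERBB2 level is argued against as the whole cause. Of the 399 genes, 128 passed at an adjusted p of 0.001 in both comparisons, where 8.33 false calls were allowed. That bound covers only the spread between these libraries, so such a response joined by differences between the lines stays open. A response that turns with the level stays open, since each form was present at 1 level. It would have to fall and then rise for 273 of the 399 genes, and rise and then fall for 126. Other differences between the HER2d16 and HER2WT lines stay open too: 5 of 815 windows of neighbouring genes shifted between them and 0 did after correction for GC content and length, and a difference not tied to a chromosome segment would leave no such trace. The receptor form itself, the difference that the design names, may explain them but was not tested apart from the line.

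Splits of 6 libraries into 3 and 3 number 10, so the share of splits with as many called genes is never under 0.1. Each split was fitted to its 6 libraries alone, so the counts differ from those of the fit of all 9 libraries. Every other split mixes the groups, so their difference enters the spread. A count of 0 there says nothing about what made the groups differ. With 1 split as large, the real one, HER2d16 against empty vector gave 6380 called genes in edgeR and the highest of the others 0. For HER2WT against empty vector 1 split was as large, with 7366 against 0, and for HER2d16 against HER2WT 1, with 7235 against 0.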

How the results depend on the processing

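The counts on both strands, the thinning of libraries to equal depth, and the removal of trends with GC content and length were chosen only after the data were seen; the other alternatives were planned. Leaving the test against a fold change of 1.5 aside, the alternatives gave 2728 to 3816 higher and 2946 to 3987 lower for HER2d16 against empty vector, 3306 to 4371 higher and 3578 to 4330 lower for HER2WT against empty vector, and 2740 to 3827 higher and 2275 to 3679 lower for HER2d16 against HER2WT, each within 1.5 times the count reported. Of the calls reported, the fewest kept with their direction were 5504 of 6717 (without HER2d16 replicate 3), 6694 of 7878 (libraries thinned) and 4928 of 6203 (without HER2d16 replicate 3), where fewer reads or libraries are used. Against a fold change of 1.5, 648 genes were higher and 864 lower for HER2d16 against empty vector, 245 and 1189 for HER2WT against empty vector, and 636 and 142 for HER2d16 against HER2WT, since that test sets aside smaller changes by construction. With library size alone as the scaling, 45.1%, 52.2% and 42.96% of the calls were higher, against 49.3%, 47.8% and 53.4% with TMM, and the largest shift of the median of all genes, -0.05, was between the forms. With the replicate number as a block there were 3443 higher and 3501 lower genes with HER2d16, 3881 and 4174 with HER2WT, and 3422 and 2984 between the forms. The labels give these libraries a shared number only, and not every same-number pair reached a correlation of 0.1. Between empty vector and HER2WT, residuals of same-number libraries correlated at 0.0405 to 0.156 and of others at -0.155 to 0.0325, and 6 of 6 libraries correlated best with their own number, a hint from the data that these numbers may pair. The third principal component (3.76% of the variance) ordered both groups by number, from 11.4 to -14.6 and from 12.4 to -18.1. With HER2d16, same-number libraries correlated at -0.0178 to 0.0185.

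Named genes kept their status, called or not called, in 8187 tests, with no called value turning direction. They lost a call in 271, 140 of them against a fold change of 1.5, gained a call in 1 and turned in 2. The values that turned, with RSEM expected counts, were -0.0631 for HER2d16 against empty vector and -0.108 for HER2d16 against HER2WT, and the cause was not tested. Lists kept their status, called or not called, in 1138 tests. They lost a call in 49, 35 of them with an estimated correlation, and gained a call in 31, 20 of them with fry. With an estimated correlation 3 lists were higher and 2 lower for HER2d16 against empty vector, 1 and 7 for HER2WT against empty vector, and 8 and 1 between the forms. Correlation between genes is not the whole cause, since camera's p also rose where the estimate lay below the preset 0.01. With HER2d16 against empty vector it rose from 1.6e-04 to 0.0073 for integrin subunits (estimate 0.0024). For TGF-beta targets (estimate -0.02) it rose from 0.0086 to 0.024. What else raised it was not tested. With fry, which does not compare a list with other genes, 7 lists were higher with HER2WT, and the cause was not tested. With library size alone, the block, trends removed and libraries left out, the adjusted p of MAPK output in HER2d16 against empty vector ranged from 0.022 to 0.079, endothelial markers from 0.021 to 0.072 and ribosomal proteins from 0.015 to 0.58. For HER2WT against empty vector the ranges were 0.022 to 0.057 for basal markers, 0.029 to 0.12 for glycolysis, 0.034 to 0.14 for interstitial matrix, 0.040 to 0.93 for mitochondrially encoded genes and 0.021 to 0.053 for histones. Between the forms they were 0.024 to 0.063 for ERBB genes, 0.0070 to 0.075 for epithelial junctions and 0.032 to 0.073 for p53 targets. Basal markers with HER2WT lost their call with the block (adjusted p = 0.0502), and p53 targets between the forms gained one (adjusted p = 0.048).

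The correlation of the HER2 responses across genes ranged from 0.71 without HER2WT replicate 1 to 0.738 without empty-vector replicate 1 when a library was left out, and was 0.75 among genes with a CPM of at least 1 in at least 3 libraries. For ERBB2 transcripts, counts in place of TPM were not run, because no transcript table was used. On simulated data with 200 changed genes, edgeR recovered 25 of 50 genes changed by 1.2-fold between HER2d16 and empty vector. That share need not carry over to the real data, where many more genes were called.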

Other observations

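In this part, removal of GC and length trends was chosen only after the result was seen. Cholesterol and lipid synthesis had 5 of 33 higher and 15 lower with HER2d16 (5 and 17 adjusted over the list alone, median log2 fold change -0.15, adjusted p = 0.024, adjusted p = 0.24 with an estimated correlation), TM7SF2, a sterol reductase, at -1.23 ± 0.15. With HER2WT it had 5 of 33 higher and 10 lower (5 and 8 adjusted over the list alone, median log2 fold change 0.00, adjusted p = 0.94), a mean of -0.04 and a downward test direction. Between the forms it had 2 of 33 higher and 13 lower (2 and 14 adjusted over the list alone, median log2 fold change -0.15, adjusted p = 0.0091, adjusted p = 0.18 with an estimated correlation). The unfolded protein and integrated stress response had 20 of 37 higher and 6 lower with HER2d16 (median log2 fold change 0.25, adjusted p = 0.0072, adjusted p = 0.058 with an estimated correlation), the chaperone HSP90B1 at 0.77 ± 0.05. With HER2WT this list had 19 of 37 higher and 11 lower (19 and 12 adjusted over the list alone, median log2 fold change 0.16, adjusted p = 0.20), a mean of -0.06 and an upward test direction, with the stress factor ATF3 at -3.09 ± 0.11. Between the forms the list had 21 of 37 higher and 6 lower (22 and 7 adjusted over the list alone, median log2 fold change 0.21, adjusted p = 0.026, adjusted p = 0.093 with an estimated correlation).

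Targets of p53 had 4 of 31 higher and 14 lower with HER2d16 (median log2 fold change -0.14, adjusted p = 0.0074, adjusted p = 0.058 with an estimated correlation), the stress gene GADD45A at -0.98 ± 0.05, and 10 of 31 higher and 13 lower with HER2WT (11 and 13 adjusted over the list alone, median log2 fold change -0.01, adjusted p = 0.68). Between the forms there were 8 of 31 higher and 15 lower (median log2 fold change -0.11, adjusted p = 0.054). They were called between the forms without HER2WT replicate 1 (adjusted p = 0.044), HER2d16 replicate 1 (0.044) or HER2d16 replicate 2 (0.045), with the replicate number as a block (0.048), and with GC and length trends removed (0.032). Ribosomal proteins had 1 of 77 higher and 7 lower with HER2d16 (1 and 5 adjusted over the list alone, median log2 fold change -0.07, adjusted p = 0.084), and were called lower without empty-vector replicate 1 (adjusted p = 0.027) or 2 (0.015). They had 34 of 77 higher and 1 lower with HER2WT (32 and 1 adjusted over the list alone, median log2 fold change 0.12, adjusted p = 0.0015, adjusted p = 0.57 with an estimated correlation) and 1 of 77 higher and 43 lower between the forms (1 and 45 adjusted over the list alone, median log2 fold change -0.16, adjusted p = 4.0e-08, adjusted p = 0.22 with an estimated correlation). Replication-dependent histones, whose transcripts lack a polyA tail, had 8 of 13 lower with HER2d16 (median log2 fold change -0.47, adjusted p = 0.0084, adjusted p = 0.063 with an estimated correlation) and 2 of 13 higher and 8 lower with HER2WT (median log2 fold change -0.66, adjusted p = 0.027, adjusted p = 0.10 with an estimated correlation). That HER2WT call ended without empty-vector replicate 1 (adjusted p = 0.053). Between the forms histones had 5 of 13 higher and 1 lower (median log2 fold change 0.04, adjusted p = 0.40).

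Endothelial markers, 6 of 13 with enough reads to test, had 1 of 6 higher and 4 lower with HER2d16 (median log2 fold change -0.83, adjusted p = 0.033, adjusted p = 0.11 with an estimated correlation), a call that ended without empty-vector replicate 3 (adjusted p = 0.072) and with GC and length trends removed (0.057). They had 1 of 6 higher and 3 lower with HER2WT (median log2 fold change -0.61, adjusted p = 0.15) and 1 of 6 higher and 1 lower between the forms (median log2 fold change 0.33, adjusted p = 0.74), where fry pointed downward (adjusted p = 0.021). Immune markers, 3 of 15 with enough reads, had 1 of 3 higher and 1 lower with HER2d16 (2 and 1 adjusted over the list alone, median log2 fold change 0.24, adjusted p = 0.81), 2 of 3 higher and 1 lower with HER2WT (median log2 fold change 0.29, adjusted p = 0.68), and 1 of 3 lower between the forms (median log2 fold change -0.06, adjusted p = 0.50). With fry, which does not compare a list with other genes, direction differed from camera's for interferon genes with HER2d16, downward at adjusted p = 0.25, and for MAPK output with HER2WT, downward at adjusted p = 0.010.

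On chromosome 20, neighbouring genes shifted together in both HER2 groups. From 296968 to 33650036, 90 genes had median log2 fold changes of 0.26 with HER2d16 and 0.29 with HER2WT, and from 43667019 to 58367507, 60 genes had -0.17 and -0.20. Between the forms the medians were -0.02 and 0.02. Windows of 50 genes were held against 1000 shuffles of gene order, 8 of 815 windows passing with HER2d16, all on chromosome 20, and 11 with HER2WT, 7 on chromosome 20, 3 on chromosome 11 and 1 on chromosome 1. After correction for GC content and length 8 and 9 passed, 8 and 7 of them on chromosome 20 and 2 with HER2WT on chromosome 1. The windows overlap, each starting 10 genes after the one before. Both stretches were merged from windows that passed in both HER2 groups. That choice favoured the signs of their medians, also by expression class. A difference in copy number may underlie the shift and stays open: it would move genes of every expression level alike, and the smallest of 12 medians, over 3 expression classes, both segments and both comparisons, was 0.0565 in the direction of its segment, in the middle class of the lower segment with HER2WT.

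ESRP1 and ESRP2, regulators of epithelial splicing, were lower in both HER2 groups, with log2 fold changes of -1.0 ± 0.06 and -0.23 ± 0.06 with HER2d16 and -0.51 ± 0.06 and -0.42 ± 0.06 with HER2WT. Changed splicing of their known targets could shift the transcript length that RSEM estimates, and the median shift of 20 targets ranked at percentile 94.3 of random lists with HER2d16 and 72.6 with HER2WT, which leaves it open. The deposited estimated length of ERBB2 was 2699 ± 11.2 bases with empty vector, 2461 ± 78.5 with HER2WT and 2429.6 ± 66.9 with HER2d16.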
